A study of Mus musculus with 24 samples.

How the data were processed

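RNA was measured by poly(A)-selected sequencing in 24 libraries of mouse mpkCCD cells, an epithelial line from the cortical collecting duct of the kidney. The libraries formed 4 groups of 6: wild-type (WT) and Gpr39 knockout (KO) cells, each given either vehicle or cpd1324, an agonist of the zinc-sensing receptor GPR39. Per the labels, the cells grew on permeable inserts for 9 days in medium lacking the vasopressin analogue dDAVP and then spent 24 h in a simpler medium. They were next exposed for 2 h to 1 µM cpd1324 or to 0.1% DMSO, both with 10 µM ZnCl2. Group and replicate number were taken from the sample titles. The labels do not say whether the 6 replicates of a group were separate cultures, so every p-value measures the spread between these samples alone. They do not name a batch, a number of knockout clones or the edited part of Gpr39 either. Library numbers ran by group, so treatment and library order could not be separated.

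The authors deposited 1 table of 12224 rows with a signal value per library and a gene length. Per the submitters' processing notes, STAR 2.7.8a, DESeq2, DESeq and the mouse assembly GRCm39 were used, without their roles. Each deposited signal, multiplied by the gene length, was a multiple of 0.1. A factor per library, between 0.754 and 1.46, then turned at least 99.8% of a library's values into whole numbers within a tolerance of 0.05. The values were therefore handled as read counts divided by a library factor, rounded and divided by gene length, the scale that the test plan had provided for. The whole reads recovered in this way came to 29.8 to 51.9 M per library. Gene lengths ran from 198 to 48896, with a median of 3590.

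Of the rows, 11498 had a single name used once. Another 393 had a name used by several rows and 333 had several names joined. These rows were tested with all the others but left out of the gene lists, since reads of near-identical genes could be split or shared there. The labels do not say whether counting used strand, so overlapping antisense genes could share reads.

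The whole table was multiplied by 1 constant, 92.1, so that the mean column total was 1000000. The results are called scaled units. The factors between libraries stayed as deposited. The 11557 rows with a mean of at least 1 scaled unit over all libraries were kept. Fold changes are differences of log2(scaled units + 0.5), which understates the change of low genes. All 24 libraries entered 1 linear model with a term per group in limma 3.58.1, with empirical Bayes moderation using a mean trend and robust settings and 20 residual degrees of freedom. All tests were two-sided. Adjusted p-values are Benjamini-Hochberg values from limma over the rows kept, and a gene was called at an adjusted p below 0.05. The contrasts were the agonist effect in WT cells, the same effect in KO cells, their difference (the interaction), and KO against WT cells under vehicle and under agonist. Errors after a fold change are moderated standard errors from limma for 6 libraries per group. Their spread was estimated over all 24 libraries, not from the compared groups alone.

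In all, 35 gene lists were fixed before the data were examined, as were the design and the settings to be varied. Of these, 34 had measured members. Some lists shared genes, so their calls are not independent. The list of mitochondrially encoded genes had 0 of 15 in the table. Each list was tested against the other genes with camera in limma, with an inter-gene correlation of 0.01 and adjustment over the lists within each contrast. Its members past the threshold were counted over all genes and also adjusted over the list alone. Camera was repeated with a correlation estimated from the data.

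Genes were named by a rule set before the data were examined. Gpr39 and Aqp2 were always named. For the agonist effects and for KO against WT cells under vehicle, the rule took the 10 highest and 10 lowest fold changes among called genes whose libraries did not overlap between groups, passing over predicted, clone-named and non-unique names. It also took up to 4 called members of each list by smallest adjusted p. For the interaction it took the 10 smallest adjusted p-values. Of the genes taken by the rule, Serpinb2, Nppb, Add2, Cox6a2, Kcne1, Ppfibp2 and Lypd6b lay near the detection limit in a group and 1 had a joined name, so these are not discussed, 1 gene list and some genes taken by the rule are not reported here, and longer lists are summarised by their counts. A gene at 0 in a whole group was given a floor of 3 reads over that group, which covers counting error only.

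The settings varied were the pseudocount (0.1 and 2), the filter (none and a mean of at least 5), median ratio and quantile scaling, a fit of the compared groups alone, moderation without trend and robust settings, a replicate block, a 1.5-fold minimum and the estimated correlation. Added after seeing the data were voom on the recovered reads, scaling of each library to the same total, leaving out each library in turn, and leaving out KO_vehicle 6 and KO_agonist 2 together. Quantile, same-total and voom values for the gene lists were added then too. GC content came by gene symbol from an annotation of GRCm38, which differs from the assembly of the deposited table, so no coordinates are given. The chromosome of a gene is the deposited one.

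The pipeline was tested on simulated data made from the means of WT cells under vehicle, the factors of all libraries and the spread over all groups. In all, 11568 rows were fitted. Few genes were changed, with rises and falls balanced and each gene drawn independently. The real agonist contrast in WT cells called 6605 genes, so the rates below do not describe it. For the agonist effect in WT cells it recovered 81.8% of 99 genes changed 1.5-fold and 94% of 100 changed 2-fold. It left 99.9% of 11369 unchanged genes uncalled, and 6.91% of its 188 calls were false. Pairs of libraries within a group were checked for duplicates: the lowest chi-square per degree of freedom of 60 pairs was 4.26, and no pair was a copy. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.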

Results

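Transcripts were counted in polarized mouse mpkCCD cells, a collecting duct epithelial line that can make the vasopressin-regulated water channel AQP2. WT cells and cells with a knockout of Gpr39, which encodes a G protein-coupled receptor activated by zinc, were given vehicle or the agonist cpd1324 at 1 µM for 2 h. Zinc at 10 µM was present in all 4 groups, and each group held 6 libraries. The series title names AQP2 trafficking and the cytoskeleton as the subject. Recovered reads per library were 37.9 ± 3.85 M (SD, n = 6) for WT cells under vehicle and 38.5 ± 4.02 M for WT cells with agonist. They were 40.3 ± 8.25 M for KO cells under vehicle and 36.2 ± 3.60 M for KO cells with agonist. Levels are in scaled units and fold changes are on the log2(scaled units + 0.5) scale.

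The targeted gene was lower in every KO library than in every WT library. Gpr39, on chromosome 1, stood at 21.6 ± 1.61 scaled units (SD, n = 6) in WT cells under vehicle and 9.37 ± 0.645 in KO cells under vehicle, 43.4% of the WT level. The log2 fold change was −1.16 ± 0.06 (SE; adjusted p = 3.37e-14 in limma). The KO libraries still held 387 to 704 Gpr39 reads each. The labels do not say which part of the gene was edited, so the level alone does not show whether a working receptor was made. With agonist, Gpr39 rose to 29.2 ± 1.33 scaled units in WT cells (0.43 ± 0.06, adjusted p = 9.63e-07) and stood at 9.40 ± 0.882 in KO cells (0.00 ± 0.06, adjusted p = 0.985). The interaction was 0.43 ± 0.08 (adjusted p = 0.000191), but with each library scaled to the same total it was 0.16 (adjusted p = 0.0923).

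Aqp2, on chromosome 15, fell in WT cells given agonist, from 17.7 ± 4.94 to 11.7 ± 1.73 scaled units (SD, n = 6; log2 fold change −0.54 ± 0.17, adjusted p = 0.00865). The WT groups overlapped: WT_vehicle 1 and WT_vehicle 2 stood at 11.9 and 12.4, within the agonist range of 9.16 to 13.5. In KO cells Aqp2 was far more abundant, at 87.3 ± 18.0 scaled units under vehicle and 66.3 ± 15.1 with agonist. The agonist effect in KO cells was −0.40 ± 0.17 and did not pass the test (adjusted p = 0.129), although it did without KO_vehicle 6 and KO_agonist 2 (−0.59, adjusted p = 0.0160). These libraries, left out after the data were seen, held the lowest vehicle and the highest agonist value of Aqp2 in KO cells (59.9 and 90.8). Leaving them out was bound to deepen the fall, so the second value does not add support for it. The interaction for Aqp2 was −0.15 ± 0.24 (adjusted p = 0.667), so the effects in WT and KO cells were not shown to differ. Actb, encoding beta-actin, had 4420 ± 330 scaled units in WT cells under vehicle and 14195 ± 1251 with agonist, against 4387 ± 222 and 4269 ± 189 in KO cells. Cxcl1, a chemokine that attracts neutrophils, went from 8.82 ± 2.23 to 313 ± 37.5 in WT cells, while its KO values were 3.70 ± 0.898 and 2.87 ± 0.577.

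**Figure D1:**
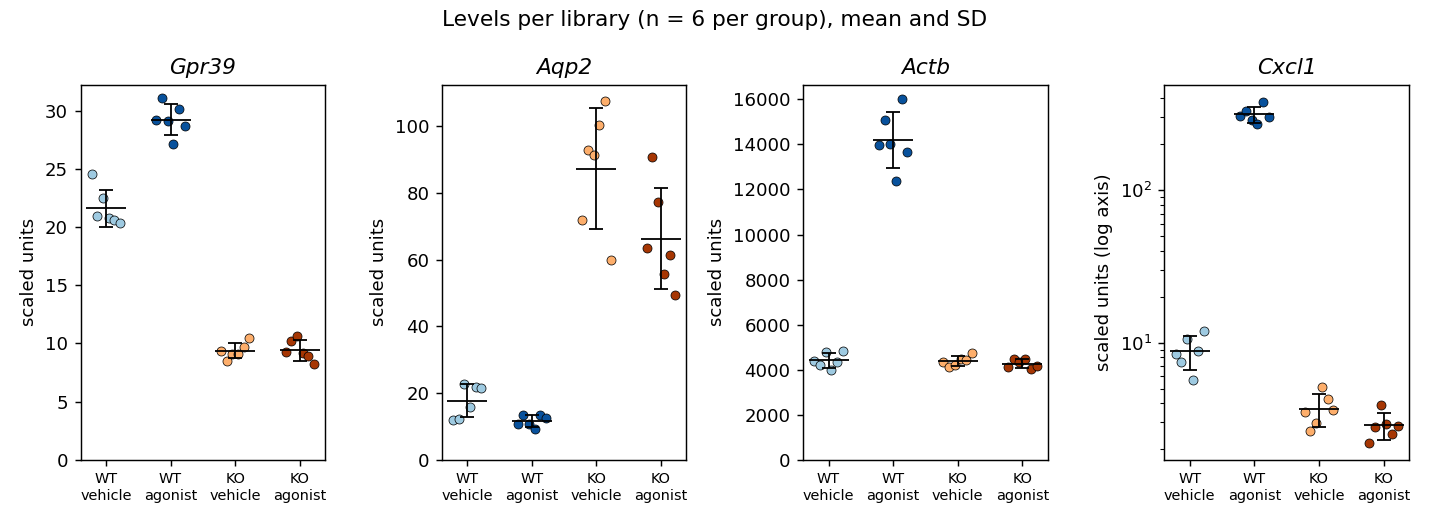
Scaled units of Gpr39, Aqp2, Actb and Cxcl1 in each of the 24 libraries by group, with mean and SD (n = 6); the axis of Cxcl1 is logarithmic. Gpr39 was lower in both KO groups, Aqp2 was higher in both KO groups, and Actb and Cxcl1 were higher in WT cells with agonist than in the other 3 groups.

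The first comparison asked what the agonist did to transcripts of cells with the receptor. Within 2 h, WT cells raised cytokines and growth factors steeply: Cxcl2, a neutrophil-attracting chemokine, by a log2 fold change of 6.12 ± 0.17 (n = 6 per group), Lif, a cytokine of the interleukin-6 family, by 5.50 ± 0.12, and Areg, a ligand of the EGF receptor, by 5.11 ± 0.16. Cxcl1 (5.10 ± 0.15), Il1a (5.07 ± 0.14), the NF-kB inhibitor Tnfaip3 (4.99 ± 0.10), the transcription factor gene Fosb (4.68 ± 0.13) and the MAP kinase phosphatase gene Dusp5 (4.39 ± 0.14) rose as well. The deepest falls were in Txnip, which encodes the thioredoxin-interacting protein (−2.91 ± 0.12; 1195 ± 221 scaled units under vehicle, 159 ± 26.4 with agonist), the chemokine-scavenging receptor Ackr3 (−2.13 ± 0.15), Clec2d (−2.09 ± 0.15) and Arrdc3, an arrestin domain protein (−1.72 ± 0.13). Arl4d (−1.66 ± 0.13), B3gnt7 (−1.62 ± 0.13), Cbr3 (−1.56 ± 0.11), Depp1 (−1.53 ± 0.23), Rasl11a (−1.52 ± 0.19) and Mylip (−1.50 ± 0.10) also fell. For each of these genes all 6 agonist libraries lay on 1 side of all 6 vehicle libraries.

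In WT cells the test called 6605 of 11557 genes, 3302 higher and 3303 lower with agonist, and 7105 had an unadjusted p under 0.05. Of the calls, 871 were at least 1.5-fold higher and 627 at least 1.5-fold lower. At 2-fold the numbers were 416 and 107. The libraries of 4244 called genes did not overlap between the groups, where chance gives 0.216% of genes. The sum of the deposited values was 1.18 times that under vehicle, and 10 genes supplied 26.5% of the rise, Actb alone 5.53%. With every library scaled to the same total the median of all genes was −0.24 instead of −0.01, so the directions of small changes depend on the scaling.

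Genes that respond to growth factor signalling rose together. All 23 measured immediate-early genes, transcribed within minutes of a stimulus, rose, with a median log2 fold change of 2.33, among them Fosl1 (4.31 ± 0.11), Ier3 (2.33 ± 0.09) and Fosl2 (2.28 ± 0.08) (camera adjusted p = 1.11e-18; adjusted p = 0.0538 with an estimated correlation). Of 22 feedback genes of the ERK pathway, 21 rose, including the EGF receptor ligand Ereg (4.07 ± 0.11) and Phlda1 (3.73 ± 0.12) (median 1.83, adjusted p = 5.72e-16). Of 18 cAMP and CREB target genes, 13 rose and 3 fell (median 1.26, adjusted p = 1.57e-06; adjusted p = 0.0543 with an estimated correlation), with the salt-inducible kinase Sik1 at 1.97 ± 0.07 and the phosphatase Dusp1 at 3.00 ± 0.12. As fixed, the cAMP list shared Nr4a1, Nr4a2, Nr4a3, Fos and Fosb with the immediate-early list and Dusp1 and Areg with the ERK list. Its call is therefore not separate evidence for a cAMP response. Of 21 NF-kB and inflammatory genes, 18 rose and 3 fell (median 1.41, adjusted p = 1.33e-11). The counts adjusted over the list alone were the same, except for 22 higher members of the ERK list and 14 of the cAMP list.

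Genes of the cytoskeleton and its transcription factors rose too. Of 20 targets of SRF and its actin-sensing coactivator MRTF, 18 rose and 1 fell (median 1.19, adjusted p = 2.37e-12). Zyx, a focal adhesion protein, rose by 1.97 ± 0.06, Actb by 1.68 ± 0.06, Srf itself by 2.03 ± 0.08 and Vcl, encoding vinculin, by 1.66 ± 0.08. Of 32 actin cytoskeleton components 26 rose and 1 fell (median 0.38, adjusted p = 2.17e-09), with Lima1 at 0.84 ± 0.04, the Arp2/3 subunit Actr3 at 1.14 ± 0.06 and the non-muscle myosin Myh9 at 1.23 ± 0.07. Actb, Actg1 and Myh9 belonged to both the SRF and the actin list. Of 18 YAP and TAZ targets 13 rose and 1 fell (median 0.46, adjusted p = 3.35e-06), including Ankrd1 (3.70 ± 0.11), the matricellular Ccn1 (3.66 ± 0.11), Cdc42ep3 (2.41 ± 0.07) and Gadd45a (2.00 ± 0.09). When adjusted over the list alone, 27 actin components rose and the other counts were unchanged.

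Of 20 principal cell and vasopressin response genes 11 fell and 1 rose (median −0.29, adjusted p = 0.0121; adjusted p = 0.456 with an estimated correlation). Sgk1, a kinase that promotes sodium channel activity, fell by 1.26 ± 0.11 on the log2 scale, Tsc22d3 by 1.10 ± 0.10 and the vasopressin receptor Avpr2 by 0.94 ± 0.13, while the keratin Krt18 rose by 1.51 ± 0.07; with the same total in every library the list was not called (adjusted p = 0.119). Of 36 genes of the AQP2 vesicle trafficking machinery 17 rose and 5 fell, with the chaperone Hspa5 at 2.93 ± 0.09, the caveolar Cav1 at 1.28 ± 0.08, the clathrin heavy chain Cltc at 0.82 ± 0.06 and Hspa8 at 0.49 ± 0.04. Their median was 0.10 (adjusted p = 0.0363; adjusted p = 0.456 with an estimated correlation) but −0.04 with quantile scaling and −0.14 with the same total. Among 18 protein kinase A and phosphodiesterase genes 6 rose and 4 fell (median 0.04, adjusted p = 0.630), with Pde4b at 2.12 ± 0.14, the anchoring protein Akap12 at 1.66 ± 0.09 and Pde7a at −0.70 ± 0.07. Of 16 zinc handling genes 5 rose and 6 fell (median −0.10, adjusted p = 0.649), with the zinc-binding metallothioneins Mt1 at −0.91 ± 0.11 and Mt2 at −0.95 ± 0.12 and the exporter Slc30a4 at 0.74 ± 0.05. Of 18 G protein signalling regulators 7 rose and 3 fell (median 0.18, adjusted p = 0.182), led by Rcan1 (1.34 ± 0.15), an inhibitor of calcineurin. The only count that differed when adjusted over the list alone was that of principal cell genes, of which 13 fell.

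All 21 unfolded protein response genes rose (median 0.83, adjusted p = 1.52e-13; adjusted p = 0.0538 with an estimated correlation), including Ppp1r15a (2.29 ± 0.08), Manf (1.29 ± 0.06) and Sesn2 (1.22 ± 0.06). Of 13 heat shock genes 12 rose (median 0.37, adjusted p = 5.55e-05; adjusted p = 0.0633 with an estimated correlation), with Hspb1 at 1.99 ± 0.11. Of 19 p53 targets 10 rose and 3 fell (median 0.35, adjusted p = 0.000629; adjusted p = 0.0871 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 1.66 ± 0.06 and the pro-apoptotic Pmaip1 at 3.29 ± 0.12. Of 17 NRF2 targets 6 rose and 6 fell (median 0.02, adjusted p = 0.694), with heme oxygenase Hmox1 at 1.59 ± 0.17. Of 5 aryl hydrocarbon receptor targets 2 rose and 2 fell (median 0.06, mean −0.05, adjusted p = 0.991). Of 24 interferon-stimulated genes 17 fell and 2 rose (median −0.43, adjusted p = 0.0160; adjusted p = 0.615 with an estimated correlation), with the antiviral Oas2 at −1.09 ± 0.18, Rtp4 at −1.10 ± 0.20 and Oasl1 at 1.00 ± 0.13. Of 30 cell proliferation genes 22 rose (median 0.35, adjusted p = 0.01; adjusted p = 0.703 with an estimated correlation), with cyclin D1 (Ccnd1) at 0.78 ± 0.17. With quantile scaling neither the interferon list (adjusted p = 0.115) nor the proliferation list (adjusted p = 0.0715) was called. Counts adjusted over the list alone were 11 p53 targets and 23 proliferation genes higher, and were otherwise unchanged.

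Most adhesion, matrix and cholesterol synthesis genes rose, while energy metabolism and clock lists were not called. Of 22 tight junction and epithelial adhesion genes 18 rose and 1 fell (median 0.42, adjusted p = 1.87e-07; adjusted p = 0.0538 with an estimated correlation), with the claudin Cldn1 at 2.58 ± 0.12 and E-cadherin (Cdh1) at 0.89 ± 0.05. Of 28 matrix and integrin genes 20 rose and 2 fell (median 0.44, adjusted p = 2.76e-06; adjusted p = 0.0538 with an estimated correlation), with Thbs1 at 2.85 ± 0.08 and the integrin Itgav at 1.70 ± 0.07. Of 16 TGF-beta targets 10 rose and 3 fell (median 0.76, adjusted p = 0.00456; adjusted p = 0.158 with an estimated correlation), with Id3 at 3.77 ± 0.17 and Ccn2 at 2.56 ± 0.12. Of 23 cholesterol synthesis genes 19 rose (median 0.54, adjusted p = 2.76e-06; adjusted p = 0.344 with an estimated correlation), with the sterol enzymes Hsd17b7 at 1.13 ± 0.07 and Msmo1 at 0.83 ± 0.08. Of 7 Wnt targets 4 rose and 2 fell (median 0.29, adjusted p = 0.221), with Sox9 at 3.43 ± 0.12. Of 27 glycolysis and hypoxia genes 8 rose and 2 fell (median 0.05, adjusted p = 0.142), with the vasodilator peptide Adm at 3.92 ± 0.16. Of 24 oxidative phosphorylation genes 1 rose and 1 fell (median −0.04, adjusted p = 0.630), and of 17 clock genes 6 rose and 7 fell (median 0.01, adjusted p = 0.898), with Dbp at −0.88 ± 0.09. Of 37 ribosomal protein genes 12 rose as deposited (median 0.10, adjusted p = 0.0363; adjusted p = 0.762 with an estimated correlation), but the median was −0.20 with quantile scaling and −0.14 with the same total. Adjusted over the list alone, 21 matrix genes rose, 1 cholesterol gene fell, 4 ribosomal genes rose, and the other counts were unchanged.

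Most markers of other kidney cells were not in the table or did not reach the filter. Of 16 intercalated cell markers 6 were measured and 3 fell (median −0.18, adjusted p = 0.386), among them Aqp6 at −0.36 ± 0.12. Of 18 proximal tubule markers 2 were measured and Lrp2 rose (median 0.30, adjusted p = 0.507). Of 14 thick limb and distal tubule markers 3 were measured and 2, Egf and Trpm6, fell (median −0.25, adjusted p = 0.450), but neither was called with quantile scaling (adjusted p = 0.135 and 0.221) or in a fit of the compared groups alone (0.0703 and 0.0922). Of 22 fibroblast markers 4 were measured and 1, Sparc, rose (median 0.37, adjusted p = 0.599), and of 18 endothelial and immune markers 2 were measured, 1 higher and 1, Csf1r, lower (median 0.16, adjusted p = 0.767). In a fit of the compared groups alone Sparc (adjusted p = 0.123) and Csf1r (0.0767) were not called, and both also lost the call without the filter on low values (0.0512 and 0.0523). With p-values adjusted over the list alone, 0 fibroblast markers rose and the other counts were unchanged.

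**Figure D2:**
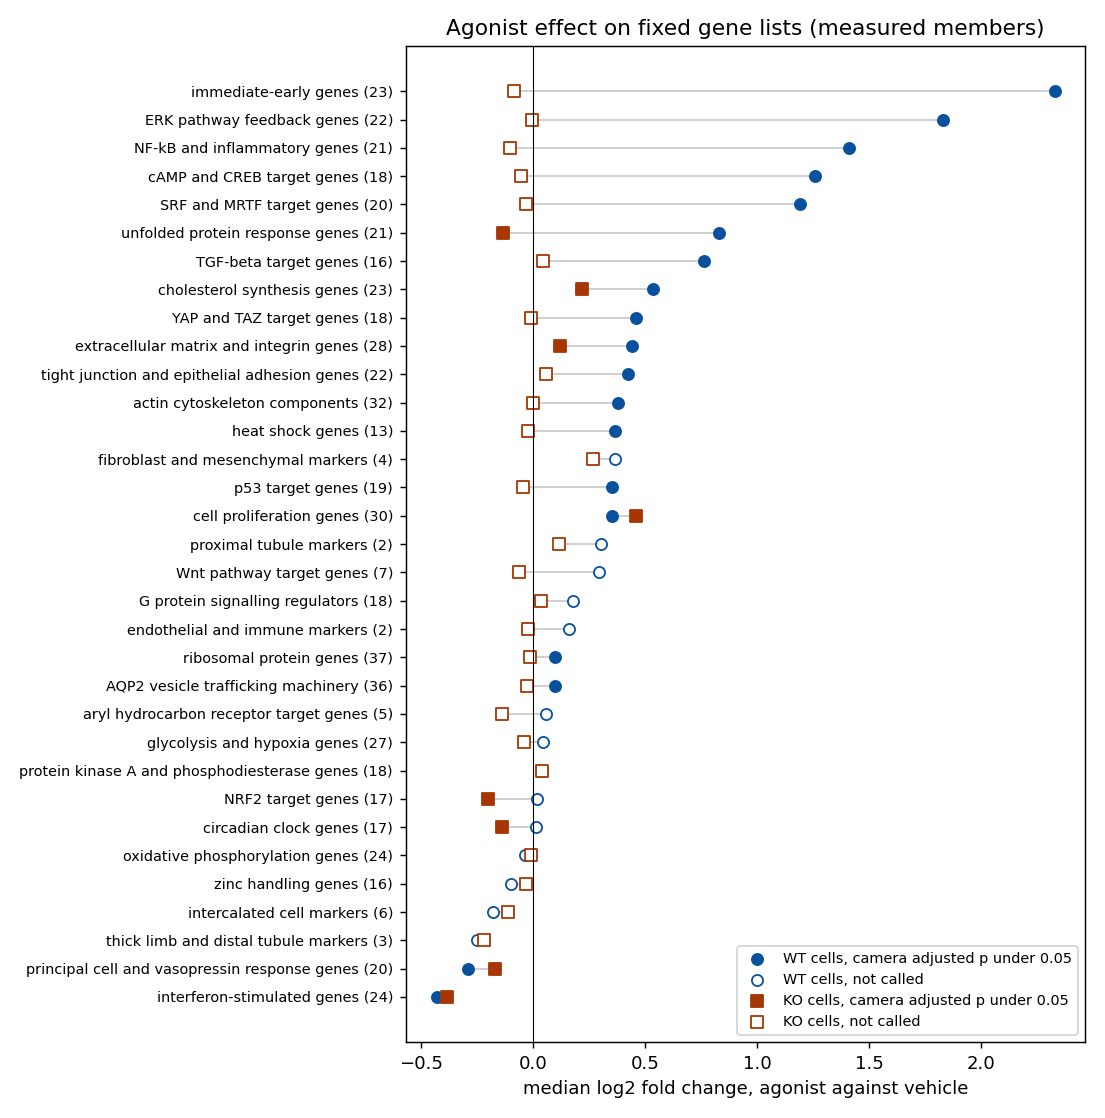
Median log2 fold change with agonist of each reported gene list in WT cells (circles) and KO cells (squares), filled where the camera adjusted p was below 0.05. The immediate-early list stood at 2.33 in WT cells and −0.08 in KO cells; the medians of the ribosomal and AQP2 trafficking lists in WT cells changed sign when every library was scaled to the same total.

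The second comparison gave the same treatment to KO cells, intended as the control for effects that do not need the receptor. Whether a working receptor remained in them was not shown. Fewer genes were called, with smaller changes. Of 30 cell proliferation genes 19 rose, with the centromere proteins Cenpa at 0.65 ± 0.11 and Cenpf at 0.55 ± 0.11 (n = 6 per group), topoisomerase Top2a at 0.56 ± 0.12 and the mitotic checkpoint kinase Bub1b at 0.58 ± 0.13. Of 24 interferon-stimulated genes 10 fell, with Rtp4 at −0.96 ± 0.20, Ifit1 at −0.74 ± 0.19 and Ifi44 at −0.75 ± 0.19. With an estimated correlation neither list was called (adjusted p = 0.506 for each). The largest rises were in Lgr6 (1.33 ± 0.24), an R-spondin receptor, Ak1 (1.26 ± 0.28), Fbln2 (1.18 ± 0.34), a matrix protein, and Ggt1 (0.84 ± 0.19). Among the 10 deepest falls, beside Rtp4, were Csn3 (−1.21 ± 0.22), a casein that stood at 1.61 ± 0.22 in WT cells, Ifit3b (−0.92 ± 0.24), and the alcohol dehydrogenases Adh7 (−0.76 ± 0.12) and Adh1 (−0.68 ± 0.13).

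In KO cells the test called 1075 of 11557 genes, 539 higher and 536 lower, and 3234 had an unadjusted p under 0.05. At least 1.5-fold changes numbered 49 higher and 32 lower, and 387 called genes had no overlap between groups, where chance gives 0.216%. The count moved with single libraries: it was 284 without KO_agonist 1, 1851 without KO_agonist 2, 589, 429, 481 and 441 without KO_agonist 3, 4, 5 and 6, and 663 and 610 without KO_vehicle 3 and 5. Without KO_vehicle 6 and KO_agonist 2 together it was 2623.

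Of the 34 lists, camera called 8 in KO cells, and with an estimated correlation 0. Of 30 proliferation genes 19 rose (median 0.46, adjusted p = 8.1e-15; adjusted p = 0.506 with an estimated correlation). Of 23 cholesterol synthesis genes 7 rose, including the regulator Srebf2 (0.22 ± 0.05) and the enzyme Mvd (0.48 ± 0.13) (median 0.22, adjusted p = 4.11e-08; adjusted p = 0.506 with an estimated correlation). Of 28 matrix genes 6 rose, with the integrin Itgb4 at 0.47 ± 0.09 and the proteoglycan Hspg2 at 0.37 ± 0.09 (median 0.12, adjusted p = 0.00377; adjusted p = 0.506 with an estimated correlation). Of 24 interferon-stimulated genes 10 fell (median −0.38, adjusted p = 2.49e-07; adjusted p = 0.506 with an estimated correlation). Of 17 NRF2 targets 6 fell, with the quinone reductase Nqo1 at −0.40 ± 0.07 and the ferritin chain Fth1 at −0.30 ± 0.07 (median −0.20, adjusted p = 2.27e-05; adjusted p = 0.506 with an estimated correlation). Of 21 unfolded protein response genes 6 fell, with Ppp1r15a at −0.37 ± 0.08, Herpud1 at −0.35 ± 0.08 and Atf4 at −0.28 ± 0.07 (median −0.13, adjusted p = 0.00238; adjusted p = 0.706 with an estimated correlation). The principal cell list was lower, with 1 of 20 members called, Elf5 at −0.53 ± 0.13, not called in a fit of the compared groups alone (adjusted p = 0.0529; list median −0.17, adjusted p = 0.0132; adjusted p = 0.706 with an estimated correlation). The clock list was lower, with 1 of 17 called, Ciart at −0.36 ± 0.06 (median −0.14, adjusted p = 0.0469; adjusted p = 0.506 with an estimated correlation). Adjusted over the list alone, 25 proliferation, 16 cholesterol, 8 matrix and 1 unfolded protein response genes rose, and 15 interferon, 10 NRF2, 11 unfolded protein response and 1 matrix genes fell.

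The immediate-early, ERK feedback, SRF and MRTF, actin and NF-kB lists, called in WT cells, were not called in KO cells. Of the immediate-early genes 0 rose and 2, Fosl1 and Myc, fell, neither of them called in a fit of the compared groups alone (adjusted p = 0.0610 and 0.0849; list median −0.08, adjusted p = 0.279), of the ERK feedback genes 0 were called, of the SRF and MRTF targets 1 rose and 1 fell, of the actin components 1 rose, and of the NF-kB genes 1, the growth factor gene Csf1 (−0.49 ± 0.11), fell (median −0.10, adjusted p = 0.0726). Without KO_vehicle 6 and KO_agonist 2, camera called the immediate-early list lower (adjusted p = 0.0286). Adjusted over the list alone, these counts were unchanged. Median, mean and test differed in sign for 5 lists in KO cells, none of them called.

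The third comparison tested whether the agonist effect differed between the genotypes. The genes with the smallest adjusted p all rose more in WT cells. They were Tnfaip3 (interaction 5.15 ± 0.14, n = 6 per group), Lif (5.55 ± 0.17), Fosl1 (4.68 ± 0.16), the inositol trisphosphate kinase Itpkc (4.05 ± 0.14), the actin-associated Palld (2.69 ± 0.10), Noct, of the deadenylase family (3.72 ± 0.14), Fosb (4.94 ± 0.18), Ifrd1 (3.95 ± 0.15), Cdc42ep3 (2.57 ± 0.10) and Ereg (4.27 ± 0.16). Their adjusted p-values ran from 4.9e-19 to 1.7e-16. The test called 4746 genes, 2481 with a higher and 2265 with a lower effect in WT cells, and 5558 had an unadjusted p under 0.05. Of the 1498 genes that changed at least 1.5-fold in WT cells, 1355 had a called interaction. With the same total in every library the median was −0.28 instead of −0.02, and 7545 genes were called, 6415 of them lower.

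Camera called 17 lists for the interaction, all with higher effects in WT cells, and 8 of them also with an estimated correlation. These 8 were the immediate-early genes (median 2.51, adjusted p = 4.9e-22; 22 of 23 members higher), NF-kB genes (1.60, adjusted p = 1.25e-14; 18 of 21), ERK feedback genes (1.499, adjusted p = 2.75e-17; 19 of 22), cAMP and CREB targets (1.21, adjusted p = 2.43e-07; 13 of 18), unfolded protein response genes (1.10, adjusted p = 1.71e-16; 20 of 21), SRF and MRTF targets (1.01, adjusted p = 5.46e-14; 18 of 20), actin components (0.41, adjusted p = 2.3e-08; 20 of 32) and YAP and TAZ targets (0.28, adjusted p = 4.5e-05; 9 of 18). Members with a lower effect numbered 2 among the cAMP targets, 2 among the YAP targets and 1 among the NF-kB genes. The immediate-early, ERK and cAMP lists shared genes, as did the SRF and actin lists, so these calls are not independent. The tight junction list (14 higher, 1 lower; median 0.44, adjusted p = 1.02e-06) and the heat shock list (9 higher; 0.44, adjusted p = 5.47e-05) each had an adjusted p = 0.0688 with an estimated correlation. The TGF-beta list (10 higher, 3 lower; 0.57, adjusted p = 0.00618) had an adjusted p = 0.164 with an estimated correlation. The matrix list, 14 higher and 2 lower, had a median of 0.21 (−0.05 with the same total; adjusted p = 0.0005; adjusted p = 0.150 with an estimated correlation). The p53 list, 9 higher and 3 lower, had a median of 0.16 (−0.10 with the same total; adjusted p = 0.00192; adjusted p = 0.136 with an estimated correlation). For the AQP2 trafficking list, 15 higher and 3 lower, the median was 0.14 (−0.14 with the same total; adjusted p = 0.0204; adjusted p = 0.402 with an estimated correlation). For cholesterol synthesis, 13 higher and 2 lower, it was 0.32 (adjusted p = 0.00582; adjusted p = 0.738 with an estimated correlation). For ribosomal proteins, 8 higher, it was 0.14 (−0.25 with quantile scaling; adjusted p = 0.0227; adjusted p = 0.840 with an estimated correlation). The principal cell (−0.14, adjusted p = 0.231), interferon (−0.04, adjusted p = 0.928) and proliferation lists (−0.08, adjusted p = 0.450) were not called. Adjusted over the list alone, 23 immediate-early genes, 14 cAMP targets, 11 YAP targets, 11 heat shock, 15 matrix, 14 cholesterol and 6 ribosomal genes had a higher effect in WT cells and 5 AQP2 trafficking genes a lower one.

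**Figure D3:**
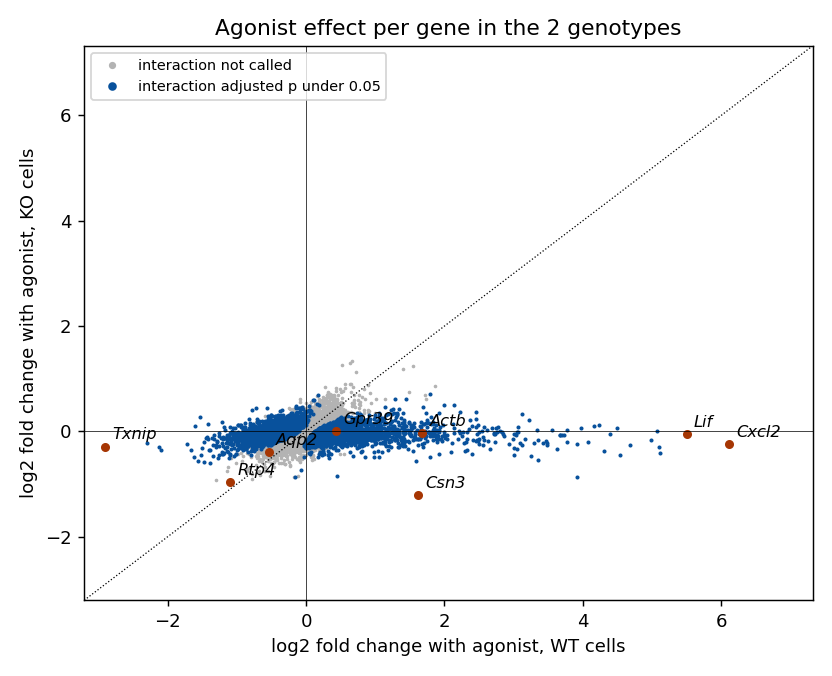
Log2 fold change with agonist of each gene in WT cells (horizontal) and KO cells (vertical), with genes called for the interaction in blue. Cxcl2 and Lif lie far to the right and Txnip far to the left, with KO values of −0.24, −0.05 and −0.29, while Rtp4 fell in both genotypes.

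The WT and KO effects shared no libraries, and across all genes their correlation was 0.162 with a jackknife error of 0.0995 (covariance 0.0143). Genes are not independent replicates. Called in both, 258 genes were higher in both genotypes where independent calls give 154, and 250 were lower in both where they give 153. Another 126 genes rose in WT and fell in KO cells, and 45 did the opposite.

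The fourth comparison set KO against WT cells under vehicle. Aqp2 was higher in KO cells by a log2 fold change of 2.29 ± 0.17 (n = 6 per group), as were the ATP-gated channel P2rx1 (3.26 ± 0.17), the thiazide-sensitive cotransporter Slc12a3 (2.77 ± 0.15) and Stk39, a kinase that acts on such cotransporters (2.52 ± 0.16). Csn3 (2.87 ± 0.22), Oas1f (2.49 ± 0.16), Cyp2f2 (2.49 ± 0.19) and Cyp4b1 (2.31 ± 0.13) were higher too. Scand1 was almost lost, at 478 ± 31.1 scaled units in WT and 6.33 ± 0.824 in KO cells (−6.14 ± 0.09), and the ammonia transporter Rhcg (−4.50 ± 0.09), Limch1 (−4.44 ± 0.11), Asb4 (−4.11 ± 0.08), Trim35 (−4.02 ± 0.16), the uroplakin Upk3a (−3.81 ± 0.18) and N-cadherin (Cdh2, −3.78 ± 0.18) were lower. Micu2, a regulator of mitochondrial calcium uptake, and the decapping factor Dcp1b had 0 reads in all 12 KO libraries. Against a floor of 3 reads over the vehicle group, Micu2 was at least 4647-fold lower than in WT cells and Dcp1b at least 336-fold lower.

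The test called 5525 genes, 2762 higher and 2763 lower in KO cells, and 6207 had an unadjusted p under 0.05. Of the calls, 421 were at least 1.5-fold higher and 492 at least 1.5-fold lower. The libraries of 3138 called genes did not overlap, where chance gives 0.216%. With agonist in both genotypes, 7406 genes differed, 3695 higher and 3711 lower in KO cells, 7770 with an unadjusted p under 0.05. There Gpr39 stood at −1.59 ± 0.06 (adjusted p = 1.1e-17) and Aqp2 at 2.44 ± 0.17 (adjusted p = 3.07e-12), and with the same total the median of all genes was 0.28 instead of 0.01. The labels name 1 knockout genotype, so differences between the lines need not stem from the receptor.

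Under vehicle, camera called 2 of the 34 lists, and 0 with an estimated correlation. Of 23 cholesterol synthesis genes 19 were lower in KO cells, among them Srebf2 (−0.55 ± 0.05) and Idi1 (−0.94 ± 0.10) (median −0.38, adjusted p = 5.05e-05; adjusted p = 0.973 with an estimated correlation). All 5 aryl hydrocarbon receptor targets were higher, with Tiparp at 1.25 ± 0.07 and Cyp1b1 at 0.79 ± 0.08 (median 0.40, adjusted p = 0.00583; adjusted p = 0.538 with an estimated correlation). Principal cell genes were mixed, with 5 higher and 8 lower of 20 (median −0.06, adjusted p = 0.746): Hsd11b2, which inactivates glucocorticoids, was higher (1.94 ± 0.12), while the sodium channel subunit Scnn1b (−1.83 ± 0.13) and St6gal1 (−1.44 ± 0.08) were lower. Intercalated cell markers went both ways, with Car2 at 1.00 ± 0.08 and Aqp6 at 0.89 ± 0.12 against the lower Rhcg (2 higher, 3 lower of 6; median −0.31, adjusted p = 0.681). Both measured proximal tubule markers were lower, Ass1 at −1.35 ± 0.06 and Lrp2 at −0.61 ± 0.13 (median −0.98, adjusted p = 0.0575). Of 24 interferon-stimulated genes 6 were higher and 1 lower (median 0.26, adjusted p = 0.231), with Oasl1 at 1.55 ± 0.13. The matrix protein Fn1 was higher (2.06 ± 0.15), and Id3 (−1.77 ± 0.17), Cxcl1 (−1.14 ± 0.15) and the G protein regulator Rgs2 (−1.50 ± 0.17) were lower. Adjusted over the list alone, these counts were unchanged.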

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

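The tests without KO_vehicle 6 and KO_agonist 2 and of a remaining receptor were chosen after the result was seen.

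The genotypes answered the agonist differently, by a test of the difference itself: 4746 genes had a called interaction. It came to 0.43 for Gpr39, 5.15 for Tnfaip3, 5.55 for Lif, 4.68 for Fosl1, 4.05 for Itpkc, 2.69 for Palld, 3.72 for Noct, 4.94 for Fosb, 3.95 for Ifrd1, 2.57 for Cdc42ep3 and 4.27 for Ereg. The median interaction of called lists was 2.51 for immediate-early, 1.60 for NF-kB, 1.499 for ERK feedback, 1.21 for cAMP and CREB, 1.10 for unfolded protein response and 1.01 for SRF and MRTF genes. It was 0.57 for TGF-beta targets, 0.44 for heat shock and for tight junction genes, 0.41 for actin components, 0.32 for cholesterol synthesis and 0.28 for YAP and TAZ targets. Lower ones were 0.21 for matrix genes, 0.16 for p53 targets and 0.14 for ribosomal proteins and for AQP2 trafficking genes. With an estimated correlation the TGF-beta, heat shock, tight junction, cholesterol, matrix, p53, ribosomal and AQP2 trafficking lists lost their call (adjusted p from 0.0688 to 0.840). With the same total in every library the median was −0.05 for matrix genes, −0.10 for p53 targets, −0.14 for AQP2 trafficking genes and −0.13 for ribosomal proteins, which stood at −0.25 with quantile scaling.

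In 100 splits of the same libraries, the real one included, only the real split called as many genes in each comparison. With so few splits the share of the real one cannot fall below 1 in 100. The splits also cannot address library order, which ran by group. For the interaction they shuffled treatment within both genotypes, so they do not test a difference between genotypes. The real counts and the highest others were 6605 and 4151 for the agonist in WT cells, 1075 and 1 for the agonist in KO cells, 4746 and 839 for the interaction, 5525 and 2559 for KO against WT cells under vehicle, and 7406 and 5043 under agonist.

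KO cells, with 43.4% of the Gpr39 transcript, still differed by a small amount between agonist and vehicle, with 1075 genes called. The count was 284 without KO_agonist 1, 441 without KO_agonist 6 and 1851 without KO_agonist 2. How far this difference rests on single libraries stays open. GC content as the whole cause is argued against. After its removal the fold changes of the called genes kept a slope of 0.952 ± 0.0332 (jackknife). Without KO_vehicle 6 and KO_agonist 2 together, 2623 genes were called, 1038 of them shared with the 1075. Both were picked after seeing the data, and leaving out either alone raised the count (1581 and 1851). Such a test could hardly give fewer calls, so it shows only that most calls did not need these libraries. A culture state that also varied among WT replicates (a share of 0.324 of their residual variance) stays open: with its score as a covariate the slope was 0.578 ± 0.0690 and 12 genes were called (0 to 128 with 1 library left out), as the changes shrank while their median SE went from 0.0718 to 0.0662. That slope lies above the bound of 0.5 set beforehand, but the score correlated 0.832 with treatment in KO cells, a value seen afterwards, so covariate and treatment cannot be told apart. Across all genes, the axis behind the score, taken from WT libraries alone, correlated −0.649 ± 0.0832 (jackknife) with the KO fold changes. The sign of such an axis is arbitrary. The KO difference thus ran in part along variation seen among WT replicates, which does not show its cause. Signalling through a remaining receptor may contribute and was not decided: immediate-early genes had a KO median of −0.08 ± 0.161 against 2.33 in WT cells, and in a second test, chosen after that, fold changes of the called genes correlated 0.424 ± 0.128 between KO and WT cells.

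Of 166 groups of 6 values tested for a sample far from the others, 6 had one, where chance gives 8.3, and 3 of these were KO_vehicle 6. WT_vehicle 2 had 30.4 M recovered reads, with the others at 37.6 to 41.0 M. KO_vehicle 6 had a mean log2 value of 6.71 for AQP2 trafficking genes (others 6.58 to 6.59), 7.64 for oxidative phosphorylation genes (others 7.87 to 7.98) and 10.15 for ribosomal protein genes (others 10.37 to 10.44). KO_agonist 6 had 10.21 for ribosomal protein genes (others 10.33 to 10.39), and KO_agonist 1 had 1.44 for thick limb markers (others 1.59 to 1.65). Pairs with KO_vehicle 6 differed by a chi-square per degree of freedom of 88.1 to 106, and the other KO_vehicle pairs by at most 16.4.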

How the results depend on the processing

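The voom, same-total and leave-one-out settings, the one without KO_vehicle 6 and KO_agonist 2, and quantile values for lists were added after the data were seen; the rest were set before. Across all settings, 169 counts of called genes stayed within 1.5 times the reported one and 15 did not. Of values for named genes, 4154 kept direction and call, 60 lost the call, 1 gained it and 6 reversed. Of values for lists, 866 kept both, 43 lost the call, 13 gained it and 2 reversed. For lists, direction is that of the camera test against the other genes. A median could thus change sign without being counted as reversed, as for matrix genes and p53 targets in the interaction with the same total. All 26 overlap values stayed within the jackknife error. That error was computed from the 24 leave-one-out values among them, so those could hardly exceed it. Except where the construction shows it (a fold minimum, other libraries), the cause was not tested. Voom called 6574, 1126, 4732, 5584 and 7360 genes for the agonist in WT cells, in KO cells, the interaction, KO under vehicle and KO under agonist. The table holds no mitochondrial genes. In the simulation 81.8% of 1.5-fold changes were recovered for the agonist in WT cells, but it changed far fewer genes than the real contrast called.

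A 1.5-fold minimum left 1498, 81, 1393, 913 and 2093 genes in the same order. The same total in every library gave 7545 interaction calls (1130 higher, 6415 lower, against 2481 and 2265), 1433 higher and 6944 lower in WT cells (3302 and 3303), 643 and 318 in KO cells (539 and 536), and 7272 and 1726 for KO under agonist (3695 and 3711). With quantile scaling the splits were 2694 and 4128 in WT cells, 1994 and 3114 for the interaction, and 4518 and 2991 for KO under agonist. Without KO_vehicle 6 and KO_agonist 2, 2623 genes were called in KO cells, 1038 of them shared with the 1075. Leaving out 1 library gave 284 to 1851 in KO cells: 284 without KO_agonist 1, 1851 without 2, 589 without 3, 429 without 4, 481 without 5, 441 without 6, 663 without KO_vehicle 3 and 610 without KO_vehicle 5. The other ranges were 6141 to 7494 in WT cells, 4452 to 5357 for the interaction, 5149 to 6065 for KO under vehicle and 7124 to 8109 under agonist. With a replicate block the counts were 6593, 1122, 4732, 5513 and 7404, no list call changed and 5 named genes lost their call. Same-numbered libraries correlated from −0.28 to 0.49, and at most 2 of 6 libraries of a comparison correlated best with their own number. Pairing by number was thus not shown, but these values do not exclude it. A fit of the compared groups alone has no interaction value.

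Reversed in WT cells were Rpl4 (−0.17 with quantile scaling, −0.0623 with the same total), Rpl18 (−0.17, −0.0231) and Rps2 (−0.14, −0.0300). With quantile scaling the ribosomal list was called lower (adjusted p = 5.32e-05 in WT cells, 1.28e-05 for the interaction). Adjusted p-values of lists that lost their call with it were, in WT cells, 0.708 for AQP2 trafficking, 0.115 for interferon and 0.0715 for proliferation, and for the interaction 0.604 for AQP2 trafficking and 0.0714 for cholesterol. Gained were oxidative phosphorylation (0.000458 in WT cells, 0.00117 for the interaction), NF-kB (0.0395) and tight junctions (0.0192) in KO cells, and proximal tubule (0.0474) in KO under vehicle. With the same total, lost in WT cells were principal cell (0.119), AQP2 trafficking (0.165), interferon (0.311) and ribosomal (0.955), and lost for the interaction AQP2 trafficking (0.0838) and ribosomal (0.775). Gained were Wnt (0.0435) and glycolysis (0.0264) in WT cells, glycolysis for the interaction (0.00935), NF-kB in KO cells (0.0229) and proximal tubule in KO under vehicle (0.0307). Without KO_vehicle 6 and KO_agonist 2, immediate-early and oxidative phosphorylation (0.0286 each) and ribosomal genes (0.00844) were gained in KO cells.

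With an estimated correlation, lost in WT cells were immediate-early, unfolded protein response, tight junction and matrix genes (0.0538 each), cAMP (0.0543), heat shock (0.0633), p53 (0.0871), TGF-beta (0.158), cholesterol (0.344), principal cell and AQP2 trafficking (0.456 each), interferon (0.615), proliferation (0.703) and ribosomal (0.762). In KO cells all 8 were lost (0.506 for proliferation, matrix, cholesterol, NRF2, interferon and clock, 0.706 for principal cell and unfolded protein response). For the interaction these were heat shock and tight junction (0.0688 each), p53 (0.136), matrix (0.150), TGF-beta (0.164), AQP2 trafficking (0.402), cholesterol (0.738) and ribosomal (0.840). In KO under vehicle they were aryl hydrocarbon receptor targets (0.538) and cholesterol (0.973).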

Other observations

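The gene families in the opening paragraph, and the tests of receptor loss for chromosome 6 and of library order, were chosen after the result was seen.

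Genes of several families that were not themselves fixed lists changed in WT cells given agonist (log2 fold change ± SE). Some members were already counted in fixed lists. Among them were Areg, Ereg, Hbegf and Lif in the ERK feedback list and Klf4, Klf6, Klf10 and Btg2 in the immediate-early list. The families were built around genes already seen to change, so their counts and medians describe them and no test of them is given for WT cells. All 5 measured genes of the plasminogen activator system rose, with urokinase Plau at 1.56 ± 0.10, its receptor Plaur at 2.56 ± 0.11 and Plat at 1.14 ± 0.08 (median 1.56). All 4 arrestin domain genes fell (median −1.35), among them Arrdc2 at −0.99 and the already described Txnip and Arrdc3. Of 9 mRNA decay factors 8 rose (median 0.52), with Noct at 3.49 ± 0.10, Zc3h12a at 2.46 ± 0.09 and Btg2 at 2.47 ± 0.13. Of 7 growth factors of the EGF family 4 rose, with Hbegf at 3.04 ± 0.12 and Nrg1 at 0.83 ± 0.08 beside Areg and Ereg. In that family 2 fell, Btc at −0.58 ± 0.12 and Egf, whose call was lost with quantile scaling (adjusted p = 0.135). The family median was 0.83, the value of Nrg1. Of 9 Kruppel-like factors 7 rose and 1 fell, with Klf6 at 2.23 ± 0.11 (median 0.51). Of 14 histone methylation enzymes 6 rose and 3 fell, with Kdm6b at 1.65 ± 0.07 and Ezh1 at −0.72 ± 0.06 (median 0.11). Of 5 interleukin-6 family cytokines and receptors 3 rose and 1 fell (median 0.15). These were the cytokine Lif and the receptor genes Il6st, Osmr, Il6ra and Il11ra1. In KO cells the medians of these families lay between −0.19 and 0.09. The lowest was that of the EGF family growth factors, with a camera p of 0.0153 at a preset correlation. Its camera adjusted p was 0.122 over 8 families, FOXO targets included, and 0.866 with an estimated correlation.

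Depp1, Txnip, Arrdc3 and Bmf (−1.42 ± 0.10), genes that FOXO transcription factors can activate, fell in WT cells. Lower FOXO activity may be a candidate explanation: among 11 other FOXO targets, fixed before they were tested, 7 fell and 2 rose (median −0.29, camera p = 0.0159 with a preset correlation of 0.01). With an estimated correlation camera gave p = 0.101, or adjusted p = 0.140 over this and the 7 families above, so the hypothesis rests on the preset. In KO cells Bmf stood at 0.15 (adjusted p = 0.338).

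In the KO line, genes of chromosome 6 were lower than in WT cells under vehicle. Their median was −0.33 over 527 genes, 376 of them called lower and 38 higher. Within each library, the mean log2 level of chromosome 6 genes was also compared with the mean of all other genes. That difference of means was at most −0.26 in each KO library and at least −0.04 in each WT library. Gene length, GC content and expression level are argued against: of 1000 matched sets from other chromosomes the lowest median was −0.0187. A lower dose of the whole chromosome in all or some KO cells may account for it, since its genes before and after the middle of its gene order were both lower, at −0.205 and −0.40, although unequally. Chromosome 10 was also lower in both parts (−0.17 and −0.16), chromosome 13 only before its middle (−0.50, then 0.09), and chromosome 8 was higher in both (0.14 and 0.23), so the shift is not particular to chromosome 6. Receptor loss as the cause cannot be told apart from a feature of the line, because the labels name 1 knockout genotype.

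Genes with the largest KO differences also lay beside each other: of 66 genes changed at least 4-fold, 9 had another such gene among the next 2 measured on either side, and the highest of 1000 random sets was 8 (median 2). Neighbours included Scand1 and Cnbd2 on chromosome 2 and Sipa1l2, Ntpcr and Map3k21 on chromosome 8, all lower, P2rx1 and 4732414G09Rik on chromosome 11, both higher, and on chromosome 14 Clu (2.09) and Trim35 (−4.02), which moved in opposite directions. Clonal events at single loci are a candidate explanation, on this count of 9. The random sets were drawn evenly from all placed genes. They do not allow for neighbours that share reads or change together for other reasons, or for the shifts of whole chromosomes. The count therefore cannot tell clonal events from these.

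Interferon-stimulated genes were lower with agonist in both genotypes, with medians of −0.43 in WT and −0.38 in KO cells and no called interaction of the list (adjusted p = 0.928; 5 of 24 members had one, 3 with a higher and 2 with a lower effect in WT cells), although the calls were lost with an estimated correlation (adjusted p = 0.615 in WT and 0.506 in KO cells), and in WT cells also with quantile scaling (0.115) and the same total in every library (0.311). GC content is argued against as the whole cause, since the KO median kept 1.12 ± 0.118 of its size after correction. With the culture state score as a covariate it kept 0.818 ± 0.304 of its size, above the bound of 0.5 set beforehand, and the WT median went from −0.43 to −0.41, but the score correlated 0.832 with treatment in KO cells, a value seen afterwards, so covariate and treatment cannot be told apart. Vehicle and agonist library numbers interleaved in 0 genotypes, so treatment and library order cannot be told apart. An effect of the compound that needs no GPR39 may remain, and with 1 compound and 1 dose it was not tested.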
